A study of Arabidopsis thaliana with 4 samples.

How the data were processed

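ChIP-seq with FLAG-M2 agarose beads was done on seedlings fixed with 1% formaldehyde for 20 min, with 2 h of incubation, per the labels' protocols. Groups were taken from the labels: FLAG-RGA wild type, FLAG-rga11 mutant, and a control for each, with 1 library per group. The deposited peaks and summits of both tagged lines were used. The controls entered only through the authors' peak calls, and no signal track was used here. As far as the labels say, peaks were called per line and not on pooled replicates. The control of the mutant call was taken from the labels, although the deposited list names it differently; which library it was stayed unsettled.

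The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.4.5, MACS2 2.2.7.1, deepTools 3.1.3 and the TAIR10 genome. Each deposited peak has a fold, the ratio of ChIP coverage over the control at the summit, which the authors' peak caller gave with a pseudocount of 1. Each also has a −log10 p and a −log10 q, likewise deposited by the authors. The deposited score of a peak is 10 times its −log10 q and was not used further. The lowest −log10 q was 3.00 in the wild-type list and 3.01 in the mutant list. Peak numbers ran to 7873 in the wild type and 778 in the mutant, above the number of peaks listed, so the lists used here hold part of the peaks that were called. The step behind the gaps is not given in the sources used here, and the peak counts and their ratio depend on it. Every peak interval was distinct, and 1 of the 506 mutant summits had no values and no peak.

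Read totals were not analysed here. The caller's fold and p both follow from ChIP coverage and control level, so solving the pair gave the number of ChIP fragments over each summit and the control level. Solutions lay within 0.001 of the deposited −log10 p for 99.98% of wild-type and 100% of mutant peaks, and the method recovered 100% of 400 simulated peaks of each kind. The simulated mutant peaks had another scaling and background than the mutant call. No simulated peak had a fold near the lowest, or a control level near the highest, of the lists, so recovery there was not tested. The genome background in the call was 14.5 for the wild type and 7.21 for the mutant, whose ChIP coverage had been scaled by 0.470. Median ChIP fragments over the summit were 62 and 107, and the lowest −log10 p was 5.05 and 6.03. A summit at background needed a fold of 2.2 in the wild-type call and 2.92 in the mutant call, so a site at background with a fold between these values was callable in the wild type alone; where control signal was above background, lower folds passed in both calls. To match coverage, wild-type ChIP coverage was scaled and control fragments thinned to the mutant call in 100 draws, and peaks passing the lowest p of the mutant list were counted. ChIP fragments were scaled and not redrawn, so the SD over draws covers the control only.

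Genes came from a table of RefSeq genes on the TAIR10.1 assembly, used for names and for which genes neighbour a summit. The 5 nuclear chromosomes of TAIR10 and TAIR10.1 were taken to share coordinates. The table gives neither strand nor sequence, which departed from the design fixed before the data were examined. Promoter, UTR, coding and intron classes and motif searches at summits were therefore not run, and a target needed a summit inside a coding gene or within 1 kb of either end. Chance was judged from 10000 random gene lists of the same size, matched on the decile of gene length plus distance to the neighbouring genes. A list was called above chance when at most 250 random lists held as many targets. With 1 library per line this describes these libraries and gives no p-value. In simulations 1.0% of unchanged lists of 20 genes were called above chance with the wild-type list and 0.5% with the mutant list.

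The 16 lists, with 243 entries for 236 genes that were all found in the table, covered known DELLA targets, GA, PIF, HLH and shade regulators, IDD and SCR/SHR regulators, brassinosteroid, auxin, jasmonate, abscisic acid, ethylene, cytokinin, cell wall, clock and light, cold and acute stress, flavonoid, abundant transcript, and seed genes with AGL80 (the list named seed storage and anther genes). They were fixed before the data were examined, as were terms for gene families, of which 19 with at least 5 genes were used. That minimum was set later. Family terms were matched to gene symbols and synonyms, so a family can hold genes of another kind and can miss members without such a name. A list of 20 rapid touch, wound and calcium response genes was composed after the strongest mutant peaks had been seen, leaving out genes at those peaks, and is reported in the closing part alone; ERF5, JAZ7 and JAZ8 of it are also in the fixed lists. Named genes followed a rule also fixed before. They were the 10 targets with the highest fold in each list, the 5 highest among shared and among wild-type-only peaks, all known DELLA targets, the 3 members of each other list with the highest wild-type fold with all its mutant targets, and the 5 highest genes at mutant-only peaks. Genes outside that rule that are named in the text were chosen after their values had been seen.

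Overlap needed at least 1 bp. It was compared with 1000 random placements of the mutant peaks on the same chromosomes and 1000 at the same distances from the ends of random genes. Shares were given exact 95% intervals, and the difference in median fold a bootstrap interval from 1000 draws. Alternatives fixed before were a −log10 q of at least 5 and 10, the upper 50% of each list by fold (its upper part), other overlap rules, other flanks, peak centres, the nearest gene and other backgrounds. Those on control signal, projected coverage, detectable fold and ranking by −log10 p were chosen after. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.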

Results

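RGA is a DELLA protein, a nuclear repressor of growth that gibberellin (GA) signalling removes through the F-box protein SLY1. Tagged RGA was mapped on chromatin of Arabidopsis thaliana seedlings by chromatin immunoprecipitation and sequencing (ChIP-seq) with anti-FLAG beads. The 4 libraries came from seedlings kept for 10 days in continuous light: FLAG-RGA wild type, FLAG-rga11 mutant, and a control for each. Every group had 1 library, so no difference between the lines has a replicate check. Both tagged lines are labelled as sly1 dP; the control for the FLAG-rga11 mutant is also labelled sly1 dP, and the control for the FLAG-RGA wild type is labelled RGA sly1 dQ. The labels describe rga11 as a mutant RGA, and the series title turns on the PFYRE subdomain of DELLA proteins and histone H2A. The comparison therefore asks which chromatin the mutant protein still marked.

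Peak lists of the tagged lines were analysed, 1 list per line, each called by the authors against a control. The names that the mutant list carries for its control differ from the labels, so which library served as its control was not settled, and each mutant fold and q depends on it. The wild-type list held 6116 peaks and the mutant list 505, and the peak numbers have gaps, so both lists hold part of the peaks that were called. Coverage worked out from the authors' fold and p gave a mean of 14.5 ChIP fragments per base for the wild type and 15.3 for the mutant. The controls had 14.7 and 7.21, and the mutant ChIP coverage was scaled down to the 7.21 of the control used for that call. The fold and −log10 q quoted for a peak are the authors' values for that peak against its control, and rank peaks only within 1 list. A gene was counted as a target when a summit lay inside it or within 1 kb of either of its ends. Positions are those of the TAIR10 genome. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only.

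The question in the wild type was which genes RGA marked. The strongest peak at a coding gene lay 922 bp from MYB74 (AT4G05100), which encodes an R2R3-MYB transcription factor. It ran from 2617359 to 2617568 on chromosome 4 with a fold of 8.28 and 127 ChIP fragments over the summit. The next were inside AT2G27402 (6.73), inside GATL6 (AT4G02130, 6.68), a galacturonosyltransferase-like gene, and inside AT5G61997 (6.67). AT1G14570 (6.41), the phospholipase D gene PLDP1 (AT3G16785, 6.41), the LysM receptor-like kinase gene LYK3 (AT1G51940, 6.40), AT5G66310 (6.38), AT4G02140 (6.32) and AT5G60460 (5.89) completed the 10 highest. Of these 10 genes, AT5G61997 alone had a wild-type peak that overlapped a mutant peak. The median peak had a fold of 2.37 and 62 ChIP fragments over its summit. In all, 6368 of 27444 coding genes (23.2%) were targets.

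Genes known as DELLA targets were over-represented in the wild-type list, with 8 of 13 marked. Random lists matched on gene size held 3.08 on average, and 41 of 10000 held as many. The marked genes were the GRAS regulator SCL3 (fold 4.38, summit 733 bp from the gene), bHLH154 (4.01), WRKY27 (3.93), the GA receptor GID1A (3.82, 28 bp), IQD22 (3.77), the GA biosynthesis gene GA20OX2 (2.91, 334 bp), the receptor GID1B (2.83, 921 bp) and the expansin EXPA8 (2.74, inside the gene). No summit within 1 kb was called at GA3OX1, XERICO, bHLH137, LBD40 or AT3G11280. The nearest wild-type summits to these lay 3377, 4539, 3269, 21627 and 2764 bp away.

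GA and growth regulators followed the same course. Of the GA metabolism and signalling genes 16 of 34 were marked (28 of 10000 random lists held as many), led by the GA-inactivating GA2OX8 (4.54), SCL3 and GID1A. The marked genes SCL3, GID1A, GID1B and GA20OX2 are also in the list of known DELLA targets, so the GA result is not independent of that one. All 5 DELLA genes were among the 16, with folds from 1.78 at RGL1 to 3.77 at GAI; they include RGA itself, where transgene fragments were not told apart from the gene. PIF, HLH and shade growth regulators had 12 of 20 marked (5 random lists), led by PRE1 (4.08), PIF5 (3.94) and PIF7 (3.36). The IDD and SCR/SHR regulators, zinc-finger and GRAS factors, had 6 of 10 marked (138), led by IDD5 (4.78), IDD9 (4.44) and IDD1 (3.21). Brassinosteroid genes had 7 of 12 marked (106), with DWF4 (3.58), ROT3 (2.88) and BAK1 (2.71) highest. Among cell wall genes 8 of 16 were marked (163), led by the cellulose synthase gene CESA3 (4.01), XTH9 (3.04) and EXPA4 (2.79). EXPA8, also marked there, is in the list of known DELLA targets too. The brassinosteroid call ended in 4 of 7 alternatives, among them a −log10 q of 5 or more (384 random lists), and the cell wall call in 4 of 7, among them the nearest gene only (370). The IDD call ended in 3 of 8, among them a background of transcription factor genes (555), and the GA and PIF calls at a −log10 q of 10 or more (332 and 575).

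Other hormone groups were also marked in the wild type. Auxin genes had 17 of 25 marked (0 random lists), led by the efflux carrier PIN3 (4.60), IAA19 (4.32) and IAA7 (4.14). Jasmonate genes had 11 of 17 marked (3), with the lipoxygenase gene LOX2 (4.90), JAZ9 (3.80) and JAZ6 (3.40) highest. Abscisic acid genes had 10 of 16 marked (17), led by the receptor gene PYL5 (5.05), CYP707A2 (3.24) and ABF3 (2.85). Clock and light genes had 7 of 12 marked (126), led by PRR9 (3.51), HYH (2.76) and GI (2.2). Cold and acute stress regulators had 7 of 8 marked (5), with CBF3 (4.02), CBF1 (3.66) and ZAT12 (3.31) highest; CBF1, CBF2 and CBF3 are neighbours, so their peaks are not independent. Ethylene genes had 6 of 15 marked (1275), with EIL1 (4.01), CTR1 (2.56) and EBF1 (2.26) highest, and cytokinin genes 5 of 11 (1019), with AHK4 (4.12), CKX5 (3.01) and ARR4 (2.46) highest. Flavonoid genes had 2 of 7 marked (5042), MYB4 (3.69) and CHS (2.16). These 3 lists were not above chance.

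Abundant transcripts, chosen to show unspecific ChIP signal, were above chance as well. There 8 of 15 genes were marked (150 random lists), led by ACT7 (3.07), ACT2 (2.45) and RCA (2.11). The list named seed storage and anther genes, silent in seedlings, had seed genes and AGL80 as its members. Of these 2 of 12 were marked, CRU3 (2.39) and CRA1 (2.29), and 8300 random lists held as many. Counting these, 12 of the 16 lists were above chance, where the threshold allows 0.4 by chance. Random lists were matched on gene length and spacing and not on expression. Unspecific signal at expressed genes was therefore not told apart from marking of these groups. At a −log10 q of 10 or more 5 lists were above chance. The calls for the DELLA target, auxin, jasmonate and cold lists held in all alternatives run. That for abundant transcripts ended in 4 of 7, as often as the brassinosteroid and cell wall calls, with a ratio to random lists of 1.09 in the upper 50% of the list by fold; the clock call ended in 3 of 8 and the abscisic acid call in 2 of 7.

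**Figure D1:**
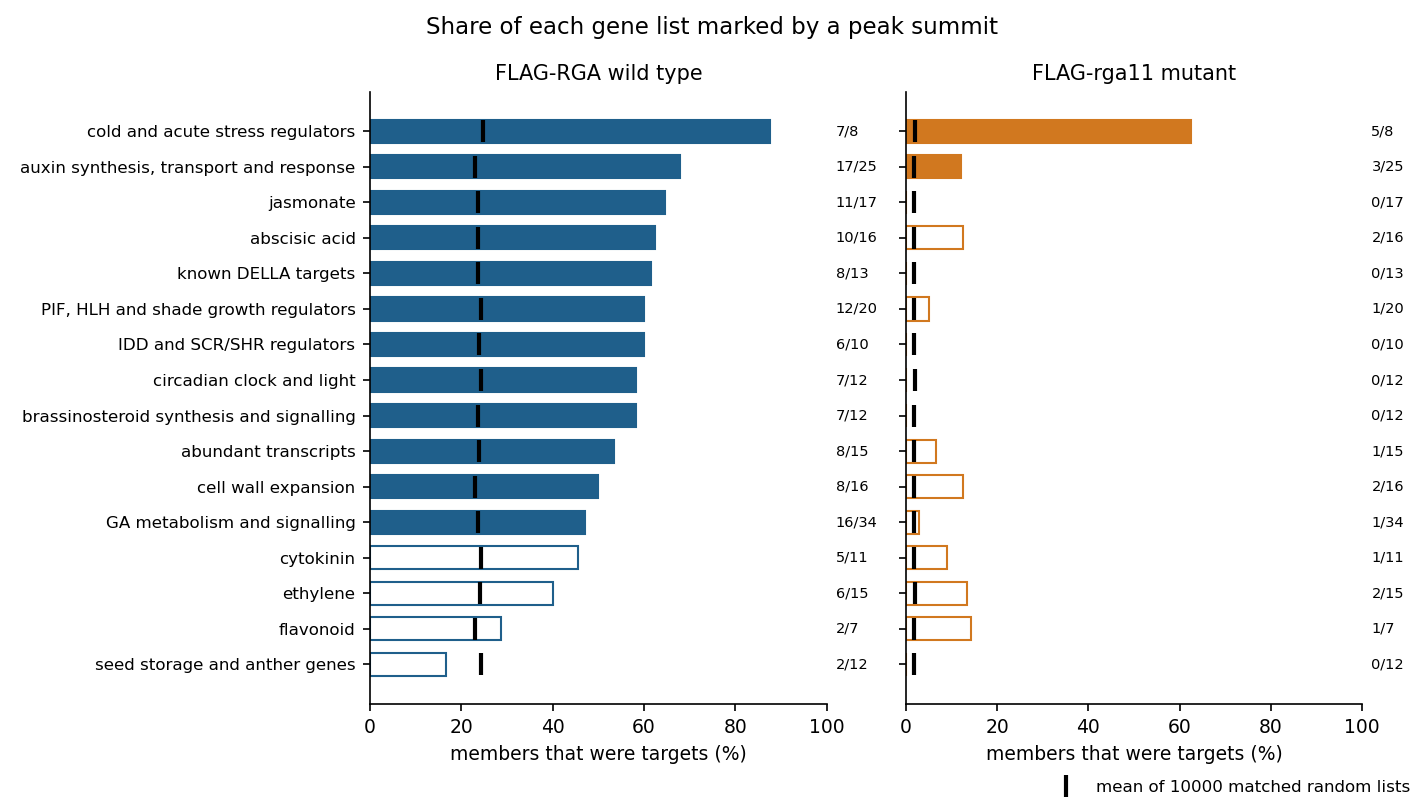
Share of members of each of 16 gene lists that were targets, in percent, for the FLAG-RGA wild-type list (left) and the FLAG-rga11 mutant list (right). Filled bars are lists that at most 250 of 10000 matched random lists equalled, black ticks are the mean of the random lists, and the numbers beside the bars are targets and genes; 12 lists were above chance in the wild type and 2 in the mutant.

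Summits of both lists were more frequent inside genes within 500 bp of a gene end than random positions. In the mutant this did not hold nearest the end. Mutant summits also lay more often between 500 and 1000 bp inside than wild-type summits. In the wild type 43.4% (42.2 to 44.7) lay inside a coding gene within 500 bp of an end and 21.8% (20.8 to 22.9) deeper inside. In the mutant these shares were 36.6% (32.4 to 41.0) and 39.0% (34.7 to 43.4), and at random positions 22.0% and 32.0%. Inside a gene within 250 bp of an end lay 8.51% (6.23 to 11.3) of mutant summits, below the 11.6% of random positions. The wild-type share there was 18.9%. Between 250 and 500 bp inside lay 28.1% of mutant summits, 24.5% of wild-type summits and 10.3% of random positions. Over 1000 bp from a gene end inside a gene lay 8.12% of mutant summits, 5.80% of wild-type summits and 16.5% of random positions. Summits outside genes but within 1 kb of one made up 22.5% (21.5 to 23.6) of the wild-type list, 9.31% (6.92 to 12.2) of the mutant list and 20.5% of random positions. Inside genes at any depth lay 65.3% (64.1 to 66.5) of wild-type and 75.6% (71.7 to 79.3) of mutant summits, against 53.9% at random. Among wild-type peaks with a −log10 q of 10 or more, 43.9% lay inside and 35.5% within 1 kb outside, so the position of wild-type summits depended on peak strength. Gene strand was not used, so starts and ends of genes were not told apart.

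**Figure D2:**
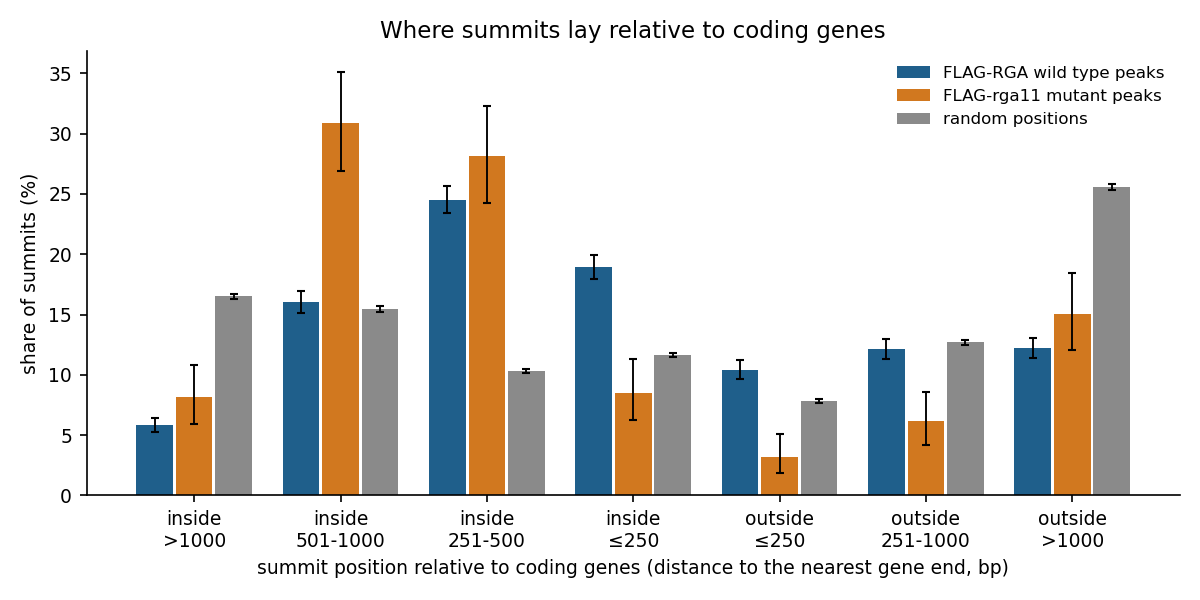
Share of summits, in percent, by position relative to coding genes for wild-type peaks, mutant peaks and 100000 random positions, with exact 95% intervals as error bars. The class inside a gene and between 500 and 1000 bp from its nearer end held 30.9% of mutant summits, 16.0% of wild-type summits and 15.5% of random positions; classes differ in width.

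Most genes marked in the wild type had no called peak in the mutant, and 361 of the 6368 did. None of the 13 known DELLA targets was marked in the mutant list, nor any IDD, brassinosteroid, jasmonate or clock gene of the lists. Of the 34 GA genes RGA alone was marked, with the same reserve about the transgene, and of the 20 PIF, HLH and shade regulators PAR1 (2.57) alone. The wild-type list had 12.1 times as many peaks as the mutant list, and 491 genes (1.79%) were mutant targets. With so few targets, random lists the size of the DELLA target list held 0.240 on average and 7847 of 10000 held none, so the empty lists were not below chance. A simulated list of 20 genes marked at 2 times the chance rate was found above chance in 62.5% of trials with the wild-type list and in 2.0% with the mutant list.

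The difference in peak number was smaller once coverage was matched. Wild-type peaks projected to the coverage and lowest p of the mutant call numbered 2332 (SD 24.0 over 100 draws), 4.62 times the mutant list. Among peaks with a fold that either call could detect at its background (at least 2.92), there were 1372 in the wild type and 178 in the mutant, a ratio of 7.71. This fold cut does not match coverage, and it sets side by side folds taken against different controls and backgrounds. Both calculations were chosen after the files had been examined.

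The strongest peak of the mutant list at a coding gene lay 726 bp from TPS7 (AT1G06410), a trehalose-6-phosphate synthase gene, at 1953724 to 1954081 on chromosome 1 (fold 4.96). A peak inside AT1G15010 (4.89) also lay within 1 kb of AT1G15015 and the sulfhydryl oxidase gene QSOX1 (AT1G15020). Next came SPL8 (4.87), GATL10 (4.60), AT1G35350 (4.59), the calmodulin-like gene TCH3 with AT2G41105 (1 peak, 4.51) and WRKY33 (4.47). Cold and acute stress regulators had 5 of 8 marked, and 0 of 10000 random lists held as many. They were WRKY33, WRKY40 (3.1), CBF1 (2.48), ZAT10 (1.98) and ZAT12 (1.94), and this call held in all 8 alternatives. Auxin genes had 3 of 25 marked (93 random lists): TAA1 (3.04), PIN7 (3.01) and IAA19 (2.93), all 3 at peaks that overlapped a wild-type peak. The auxin call ended with a −log10 q of 5 or more (2517 random lists) and of 10 or more, where no auxin gene was marked.

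The other lists were not above chance in the mutant with all peaks. Abscisic acid genes had 2 of 16 marked (317 random lists), CYP707A3 (3.57) and HAI1 (2.97). Ethylene genes had 2 of 15 (335), ERF5 (3.45) and ACS6 (2.71). Cell wall genes had 2 of 16 (353), XTH22 (4.12) and XTH4 (2.58), neither of them a wild-type target. Cytokinin and flavonoid genes had 1 each, CKX5 (3.73) and MYB4 (3.96). Of the abundant transcripts UBQ10 (1.88) alone was marked (2504 random lists), and no gene of the seed storage and anther list was. Calls were gained for ethylene in 3 of 7 alternatives (127, 120 and 176 random lists), for abscisic acid (121 and 229) and cell wall genes (140 and 200) in 2 of 7 each, and for PIF, HLH and shade regulators with a flank of 2 kb (155).

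Many of the mutant peaks coincided with wild-type peaks. Of the 505 mutant peaks 286 (56.6%, 52.2 to 61.0) overlapped a wild-type peak by at least 1 bp, and 289 of 6116 wild-type peaks (4.73%, 4.21 to 5.29) overlapped a mutant peak. Random placement gave a median of 14 overlaps, placement at the same distances from random genes gave 24, and 0 of 1000 placements of either kind gave as many as observed. Neither kind of placement kept control signal, which was over 5 times background at 47.8% of shared wild-type peaks and 4.60% of wild-type-only peaks. The excess over placement is therefore not by itself a measure of retained binding. With control signal at most 5 times background 39.8% of mutant peaks overlapped. The strongest shared wild-type peaks lay at AT5G61997, OFP16 (5.87), the RING-finger gene BRG3 (5.59), the LysM receptor-like kinase gene LYK4 (5.48) and PLS (5.43). By genes, 361 of the 491 mutant targets were also wild-type targets, where independent lists would share 114. The 114 takes account of neither gene size nor control signal, so the same limit holds for this excess. The strongest peaks of the mutant list with no wild-type peak were those at AT1G15010, AT1G15015 and QSOX1, and at AT4G27270 and AT4G27280 (4.33). With each list limited to its upper 50% by fold, 24.9% of mutant peaks overlapped, and against the 505 strongest wild-type peaks 6.14% did.

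Shared peaks were not simply the strongest wild-type peaks. Their median wild-type fold was 1.94 against 2.39 for the others, a difference of −0.44 (95% bootstrap interval −0.52 to −0.36), while their median −log10 p was higher, 13.9 against 9.17. Control signal at shared peaks was also higher, a median of 4.76 times the genome background against 1.63. The fold difference turned to 0.43 among peaks with control signal at most 2 times background, to 0.045 at most 5 times, and to 0.61 in the upper 50% of the list by fold. With the wild-type list split by fold into 5 equal parts, the share that overlapped a mutant peak was 12.3% in the lowest part, 1.72% in part 4 and 4.17% in the highest.

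**Figure D3:**
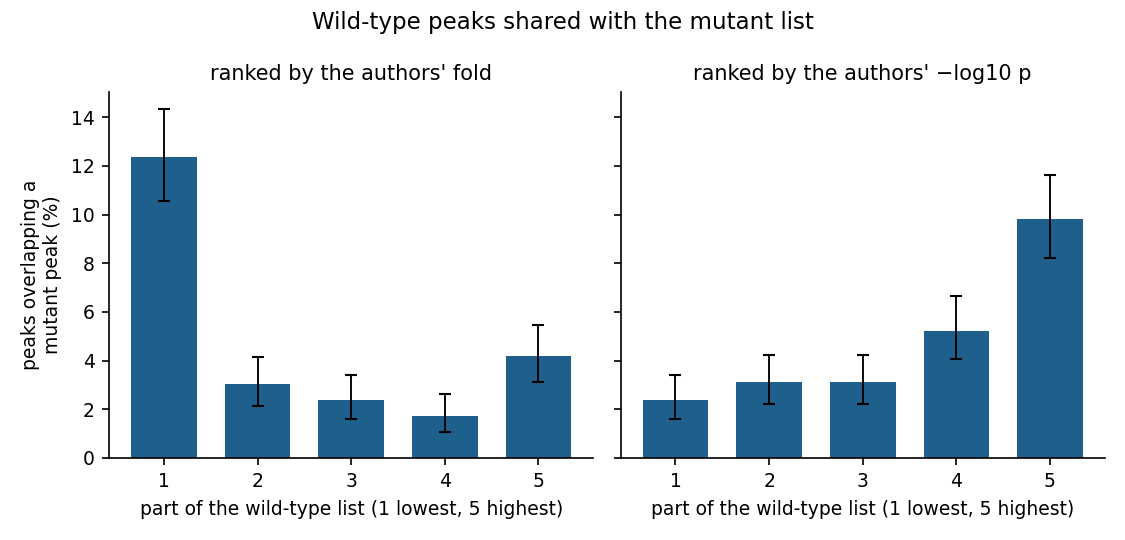
Share of wild-type peaks that overlapped a mutant peak, in percent, in 5 equal parts of the wild-type list ranked by fold (left) and by −log10 p (right), with exact 95% intervals as error bars. The lowest part by fold had 12.3% shared, and by −log10 p the share was 2.37% in the lowest part and 9.80% in the highest.

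Summits were called at RGA itself (AT2G01570) in both lines. The wild-type list had 1 inside the gene at 256708 on chromosome 2 (fold 2.19), 1 at 259120, 1552 bp away (3.73), and 1 at 261919, 4351 bp away (3.65). The mutant list had 3 inside, at 255641 (3.03), 256739 (1.78) and 257174 (2.45), and 1 at 259015, 1447 bp away (4.34). The labels do not describe the construct, and signal from a transgene copy of RGA was not tested here, so these summits do not by themselves show binding there.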

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

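The test of the dense cluster below was chosen after the cluster had been seen.

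The mutant summit list held 1 summit with no fold, p or q and no matching peak, at 3955191 on chromosome 4. It was flagged because it lies outside the peaks that the comparisons used. The same stretch of chromosome 4 held the densest 100 kb of the mutant list, with 12 peaks between 3966450 and 3999988, against 7 in the next densest. Their folds ran from 1.22 to 2.13, 1 of them overlapped a wild-type peak, no coding gene and 4 pseudogenes lay in the span, and control signal at their summits had a median of 89.5 times the genome background. Repeated or extra-copy DNA in this stretch may account for these peaks, since a median over 5 times background was set as the bound for it. No biological explanation was tested, and the difference between the FLAG-rga11 mutant line and its control at this stretch stays open.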

How the results depend on the processing

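Settings on control signal, detectable fold and projected coverage were chosen after the data had been seen; other settings were fixed before. No paired analysis was possible because each line had 1 library. Motif searches with all their alternatives, and targets from 1 kb upstream to 200 bp downstream of the start, were not run. The causes below were not tested except where the setting itself removes peaks. Wild-type peaks numbered 1788 at a −log10 q of at least 10, 3066 in the upper part of the list by fold, 1372 at a fold detectable in both calls, and 2332 or 3107 when projected to the mutant coverage with the lowest p of the mutant or the wild-type list. Mutant peaks numbered 303 and 104 at a −log10 q of at least 5 and 10, 253 in the upper part and 178 at a detectable fold.

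The share of mutant peaks overlapping a wild-type peak was 52.1% and 32.7% at a −log10 q of at least 5 and 10, 24.9% in the upper part, 48.1% for summits within 100 bp, 42.2% for reciprocal overlap, 6.14% at equal list length and 39.8% with control signal at most 5 times background. In the same order the share of wild-type peaks was 3.77%, 1.90%, 2.05%, 3.97%, 3.48%, 6.14% and 2.52%. The difference in median fold, shared minus wild-type-only, was −0.58 and −0.91 at a −log10 q of at least 5 and 10. It reversed to 0.61 in the upper part, 0.43 with control signal at most 2 times background and 0.045 at most 5 times.

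Wild-type summits inside genes made up 59.2% and 43.9% at a −log10 q of at least 5 and 10, 47.4% in the upper part and 63.3% with control signal at most 5 times background. Those just outside made up 26.6%, 35.5%, 33.7% and 23.9% in that order, 15.3% with a flank of 500 bp and 29.1% with 2 kb. Mutant summits inside genes made up 65.4% at a −log10 q of at least 10 and 71.1% in the upper part. Those just outside made up 16.2% in the upper part, 5.74% and 12.9% with flanks of 500 bp and 2 kb, and 12.8% with control signal limited.

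Lists above chance in the wild type numbered 5 at a −log10 q of at least 10 and 7 in the upper part, and families 3 in the upper part and 10 with the nearest gene only. In the mutant, lists numbered 1 at a −log10 q of at least 10, 4 in the upper part and 5 with control signal limited, and families 1 at a −log10 q of at least 10. Ratios to random lists reversed to 0.820 for the touch list in the upper part of the wild type. In the mutant they reversed to 0.0 for auxin at a −log10 q of at least 10, and for photosystem genes to 0.0 there and 0.0 in the upper part. With all mutant peaks random lists held 0.436 auxin and 0.848 photosystem targets on average. A count of 0 with fewer peaks therefore shows no change of direction. Over all settings, the above-chance call of single lists and families was unchanged in 455 cases, ended in 40, was gained in 17 and ended with a reversed ratio in 4. The unchanged cases include lists that were not above chance under either setting, whose ratio could still change direction.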

Other observations

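The touch, wound and calcium list, the tests of abundant transcripts and of summits at the stress genes alone, and the values with control signal limited were chosen after the results had been seen.

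Gene families showed further groups marked in the wild type. Of 19 families 6 were above chance, where the threshold allows 0.48 by chance, again with random lists not matched on expression. Each family holds the genes whose names matched its terms, so the counts here and in the mutant are not of complete or pure families. WRKY factors had 27 of 72 marked (88 of 10000 random lists held as many), led by WRKY47 (fold 4.70) and ZAP1 (4.53). Homeobox factors had 34 of 95 (43), led by PHB (4.40) and BLH4 (4.20). In the upper part of the list by fold the WRKY call (1308) and the homeobox call (788) ended, and the WRKY call ended also at a −log10 q of 10 or more (742) and with control signal at most 5 times background (263). TCP factors had 7 of 12 (80), led by TCP10 (2.95). Protein phosphatases 2C had 9 of 18 (160), among them PP2CA (3.07), a call that ended in 5 of 7 alternatives, up to 1333 random lists at a −log10 q of 10 or more. Genes that matched protein kinase terms had 182 of 583 marked (0), led by LYK3 (6.40). Photosystem and light-harvesting genes had 34 of 52 (0), with no fold above the 2.96 of LHCB4.3, and the call ended in the upper part of the list by fold (900 random lists) and at a −log10 q of 10 or more (290). MYB factors had 22 of 147, and 53 random lists held as few, although MYB74 had the highest fold of all targets. Heat shock proteins had 2 of 30 (156 as few). With the nearest gene only, the ratio to random lists went from 0.626 to 0.939 for MYB factors, where 6909 random lists held as many, and from 0.284 to 0.555 for heat shock proteins (9273), so neither low count held there.

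In the mutant list AP2/ERF factors had 18 of 177 marked (0 random lists), led by ERF12 (4.24) and ERF5 (3.45), a call that ended in the upper part of the list by fold (360). WRKY factors had 5 of 72 (110), with WRKY33, WRKY47 (4.19), WRKY70 (3.11) and WRKY40 highest, a call that ended at a −log10 q of 10 or more (2273). Photosystem and light-harvesting genes had 4 of 52 (114), with folds from 1.94 at LHB1B1 to 2.30 at PSBX, a call that ended in 5 of 7 alternatives. Among genes that encode no protein, 20 of 326 miRNA genes had a wild-type summit within 1 kb, where random placement gave 35.2 (SD 5.92), and MIR163 (3.90), MIR156c (3.24) and MIR166a (2.97) were among them with no coding gene as near. A summit was called at 90 of 625 tRNA genes (14.4%, 11.7 to 17.4) in the wild type and at 4 in the mutant. No chance level is given for tRNA genes, 23.2% of coding genes were wild-type targets, and the wild-type list held 12.1 times as many peaks. The counts therefore do not show preferred marking of tRNA genes.

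The mutant list was the shorter by 12.1 times. Lower coverage of the mutant call as the whole cause is argued against by the projection, which left 2332 wild-type peaks where the bound was at most 1.5 times the mutant list; the projection was chosen after the files had been examined, and its bound was written before its result was seen. Evenly weaker recovery of the same sites is argued against as well: of the 289 wild-type peaks strongest by projected p, 17.6% (13.4 to 22.5) overlapped a mutant peak, where at least 50% was the bound, likewise chosen after the files and before the result. That ranking used the wild-type control level. A different control in the mutant call, or called peaks absent from the mutant list, could also lower the share, and neither was tested. The difference of 0.43 in fold among peaks with control signal at most 2 times background goes the other way, so weaker recovery may still account for part of it. An altered choice of sites by the mutant protein, the amount of tagged protein and differences between the controls stay open as hypotheses, untested with 1 library per line.

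Mutant peaks lay at acute stress genes, where a wider class of rapidly induced genes is a hypothesis that those peaks prompted. Of the 20 rapid touch, wound and calcium response genes, 9 were marked in the mutant (0 of 10000 random lists held as many), among them MPK3 (3.46), CML38 (2.69), ERF105 (2.5) and TCH2 (1.90), and without the genes of the fixed lists 8 of 17 were; since the list was composed after the strongest mutant peaks had been seen, this is not independent evidence. With control signal at most 5 times background the mutant ratio to random lists went from 25.1 to 10.8 (24 random lists) for this list and from 32.3 to 26.1 for the cold and acute stress list, while the wild-type call, 11 of 20 (16), ended (ratio 1.1). Signal spread over gene bodies stays open. Inside a coding gene lay 75.6% of all mutant summits against 64.7% (63.5 to 65.9) of wild-type-only summits, which met the bound of separate intervals written before for this cause. Shared wild-type peaks reached 76.8%, but these are sites that mutant peaks overlap, so their share does not weigh against it. At the cold and acute stress genes alone 8 of 8 summits lay inside (100%, 63.1 to 100), too few to set them apart. These summits belong to 5 genes and are not independent, so the interval is too narrow. They also had to lie within 1 kb of a gene to be counted, unlike the wild-type-only summits. General background at abundant transcripts also stays open, as 2504 of 10000 random lists held as many mutant targets. That is at the bound of 25% within resampling spread, a margin added after the value was seen. The ratio was 0.0 with control signal at most 5 times background and in the upper part of the list by fold. These settings remove peaks with high control signal or low fold. With all mutant peaks random lists held only 0.286 abundant-transcript targets on average. A count of 0 there therefore does not weigh against this cause. The ratio of 19.0 at a −log10 q of 10 or more (516) was not above chance and does not weigh for it. All these values rest on UBQ10 alone, and true binding by the mutant protein stays open too.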
